A study of Mus musculus with 12 samples.

How the data were processed

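RNA sequencing was carried out on mpkCCDc11 mouse collecting duct cells given 50 nM control siRNA or Ctnnb1 siRNA and treated with vehicle or 1 nM dDAVP for 24 h, in 4 groups of 3 libraries. Per the labels, cells were grown for 4 days on permeable supports and kept for 24 h without serum and hormones before treatment, and libraries were strand-specific and made from total RNA depleted of ribosomal RNA. Per the submitters' processing notes, reads were trimmed with Trimmomatic after FastQC, aligned to GRCm38 (mm10) with HISAT2 and assembled with StringTie, and DESeq2 is named among the tools, without versions. Whether counting used the strand is not stated, so reads of overlapping genes, such as Gm34765 with Aqp2, Aqp5 and Aqp6, may not be told apart. The deposited table holds 25208 genes with 12 columns of unnormalised read counts, 1 per library, per the file headers. It also holds 12 columns of TPM values that the authors made with transcript length and a fixed sum per library, used here only for an alternative. Checked on the values, the count columns are whole numbers that sum to 32997720 to 48935473 per library, and each TPM column has the sum that the unit requires. All per-sample columns were used. Coordinates of named genes were taken from the RefSeq annotation of GRCm38, which held all 108 named symbols.

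The comparisons, tests, gene lists, the rule for named genes and the alternatives not listed as added were fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were filtered with filterByExpr on the group, which left 16508 genes holding 99.968% of reads, libraries were scaled by TMM, and a quasi-likelihood model with robust fitting and 1 coefficient per group was fitted to all 12 libraries. The common biological coefficient of variation was 8.26%. Each contrast was tested with the quasi-likelihood F test and Benjamini-Hochberg adjustment over all tested genes, and a gene was called at an adjusted p under 0.05. The contrasts were dDAVP against vehicle with each siRNA, Ctnnb1 siRNA against control siRNA with each treatment, the interaction, and the averages of the dDAVP and of the siRNA effects. Unless another tool is named, adjusted p-values of genes are from edgeR. CPM values are TMM-normalised. Ratios of Aqp2 counts carry 95% counting intervals, and the floor for a count of 0 is 3 counts per library.

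Genes were named by this rule. Ctnnb1 and Aqp2 were always named. For each pairwise comparison the 6 raised and the 6 lowered genes with the largest fold change were taken among called genes with a mean CPM of at least 1 and no overlap between the groups of 3 values, which chance gives for 10% of genes, leaving out predicted genes, small RNAs and pseudogenes by symbol. Up to 4 called members per fixed list were added by smallest adjusted p. For the interaction, where fewer than 3 genes were called, the 3 in each direction with the smallest p were taken as not called, and for the overlap of the averages the 5 genes per quadrant with the smallest sum of ranks. Of the 58, 63, 20 and 16 called genes so picked for dDAVP with control siRNA, dDAVP with Ctnnb1 siRNA, siRNA with vehicle and siRNA with dDAVP, 30, 32, 7 and 3 kept their call in every alternative. As an exception to the rule, only part of the picked genes are given in the report. The choice was made after the data were seen and left out some genes whose calls were lost without 1 or more libraries, so the genes given are steadier than those left out.

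The 36 fixed gene lists covered collecting duct and other kidney cell types, fibroblasts, leukocytes and endothelium, signalling by cAMP, protein kinase A, Wnt, YAP, TGF-beta, MAPK and NF-kappaB, Aqp2 trafficking and transcription, cell junctions, mesenchymal transition, cell cycle, metabolism, stress responses, p53, ribosome, lysosome, basement membrane, ion transport and signs of RNA composition. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 36 lists of a contrast, and again with an estimated correlation and with fry. Counts of called list members are from edgeR, and those of other tools were taken only for the G2 and M phase, glycolysis, interferon and ribosomal protein lists in the comparisons where they are given. The size of the dDAVP response after knockdown was measured as the total least squares slope through the origin, with a jackknife error over libraries. Exact permutation tests were run on the CPM of Ctnnb1 and Aqp2.

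The alternatives were DESeq2 1.42.0, its size factors or upper-quartile scaling in edgeR, no filter, a filter at 1 CPM in 3 libraries with a mean of 20 reads, a fit of the 2 groups compared, a replicate block, voom with sample weights, limma on log2 of TPM plus 1, and each library left out in turn. Added after seeing the data were a correction for gene length per library (known for 88.46% of tested genes), log2 TPM without 6 small structural RNAs, fry on the signed dDAVP response, the siRNA effect in libraries not used to call the dDAVP effect, the overlap without each library, lists without Ctnnb1-siRNA dDAVP replicate 3, and a list of NRF2 targets. Other splits of the libraries were refitted, all 10 for each pairwise comparison and 100 drawn for each average effect. The methods were tested on simulated data: with 200 changed genes, 36%, 74%, 94% and 100% of 1.25-, 1.5-, 2- and 4-fold changes were recovered for a pairwise comparison and 10%, 56%, 88% and 94% for the interaction. These shares hold for 200 changed genes. The adjusted threshold is stricter where fewer genes change, so they do not give the recovery for the real interaction, where 0 genes were called. The pairwise comparison had 11 false calls among 16308 unchanged genes, beside 18, 37, 47 and 50 recovered genes by fold. In a second draw of the same changes, DESeq2 recovered 163 of 200 with 31 false calls, and voom 155 with 10. Input was read with data.table (version 1.17.8), and figures drawn with Python 3.11.15 and matplotlib 3.10.9.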

Results

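Total RNA depleted of ribosomal RNA was sequenced from mouse mpkCCDc11 cells, an immortalised line from the kidney cortical collecting duct. The cells received 50 nM of a control siRNA or of an siRNA against Ctnnb1, the gene of beta-catenin, and were then exposed for 24 h to vehicle or to 1 nM dDAVP, an agonist selective for the vasopressin V2 receptor. The 4 groups held 3 libraries each. The control-siRNA vehicle libraries held 48935473, 32997720 and 45399824 counted reads (replicates 1 to 3), and the control-siRNA dDAVP libraries 39230230, 39698004 and 47452875. The Ctnnb1-siRNA vehicle libraries held 40210205, 44102656 and 43053427, and the Ctnnb1-siRNA dDAVP libraries 46142225, 44496779 and 48762950. The table held 25208 genes, of which 16508 were tested. The labels do not say that the 3 replicates of a group were separate cultures, so every p-value measures only the spread between these samples, which may be technical. Sequencing reads are not independent molecules, and the counting intervals and detection floors given here cover counting error only.

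Signs of library composition differed between groups. Small structural RNAs took 1.58% of reads in control-siRNA vehicle libraries (SD 0.319), 2.07% with dDAVP (SD 0.411), 2.18% in Ctnnb1-siRNA vehicle libraries (SD 0.0929) and 2.39% with dDAVP (SD 0.737; n = 3 each). Ctnnb1-siRNA dDAVP replicate 3 stood apart from its group. The variance against its 2 mates was 41.7 and 67.3 times that of counting error, against 5.27 to 24.5 for the other pairs. This is the chi-square per degree of freedom over genes, in which abundant RNAs weigh most. Mitochondrial ribosomal RNA took 1.52% of the reads of that library, against 0.831% and 0.464% in replicates 1 and 2 of its group. The control-siRNA dDAVP group had a mean of 0.984% (SD 0.266, n = 3), with 1.27% in its replicate 1.

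The siRNA lowered its target in every sample. Ctnnb1 (gene ID 12387, GRCm38 chromosome 9, 120933400 to 120960507) had 766, 745 and 761 CPM (read counts scaled to library size) in the control-siRNA vehicle libraries and 776, 811 and 786 CPM in the control-siRNA dDAVP libraries. It had 334, 306 and 310 CPM in the Ctnnb1-siRNA vehicle libraries and 335, 342 and 326 CPM in the Ctnnb1-siRNA dDAVP libraries. The fall was 2.39-fold with vehicle (log2 -1.26, SE 0.047, adjusted p = 6.30e-10) and 2.37-fold with dDAVP (log2 -1.24, SE 0.047, adjusted p = 7.64e-10), lower in 3 of 3 samples each time. The exact permutation test of the 3 against 3 values gave p = 0.1 (two-sided) in both treatments, the smallest p that this design allows. No effect of dDAVP on Ctnnb1 was called in control-siRNA cells (log2 0.06, adjusted p = 0.601) or in Ctnnb1-siRNA cells (log2 0.08, adjusted p = 0.506).

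**Figure D1:**
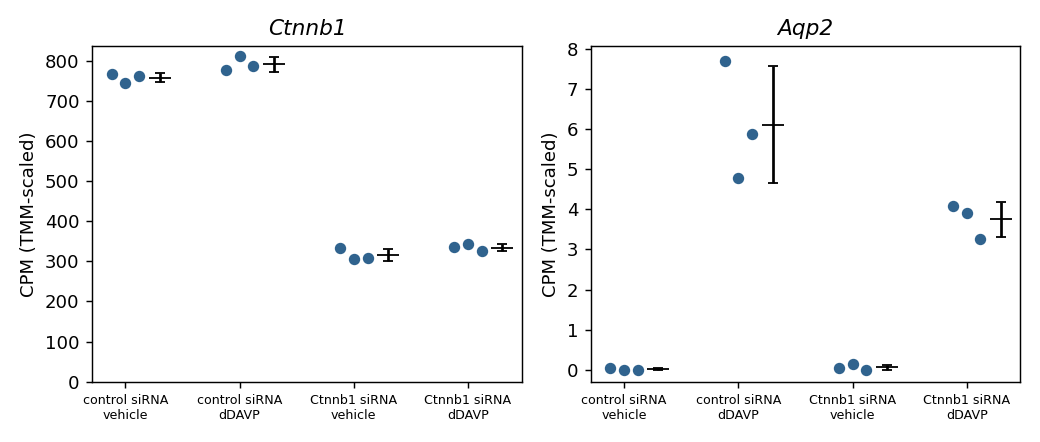
Normalised read count (CPM) of Ctnnb1 and Aqp2 in each of the 12 libraries by group, with dots for libraries and bars for the mean ± SD (n = 3). Ctnnb1 lies between 306 and 342 CPM after its siRNA and between 745 and 811 CPM after the control siRNA.

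The first comparison asked which genes respond to V2-receptor stimulation in control-siRNA cells. In control-siRNA cells dDAVP raised Aqp2 (gene ID 11827, chromosome 15, 99579056 to 99584545), the vasopressin-regulated water channel, from 2 reads in the 3 vehicle libraries together to 770 reads in the 3 dDAVP libraries. This is a ratio of 392 (95% counting interval 108 to 3240), or 0.0136 CPM (SD 0.024) against 6.11 CPM (SD 1.47, n = 3 each), with an adjusted p of 2.20e-07. In vehicle replicates 2 and 3, which had no Aqp2 read, a count of 0 allows up to 0.0895 and 0.0651 CPM, and the log2 fold change of Aqp2 ranged from 3.21 to 11.03 over all alternatives. The low end is from log2 of TPM plus 1, where the added 1 shrinks the change of a gene near 0. Pde4b (gene ID 18578, chromosome 4, 102087332 to 102607275), a cAMP phosphodiesterase, rose 8.94-fold from 4.07 CPM (SD 1.498) to 35.6 CPM (SD 0.515; log2 3.16, SE 0.17, n = 3 each). Baiap2l2 (gene ID 207495, chromosome 15, 79258195 to 79285556) rose 7.69-fold (log2 2.94, SE 0.13, adjusted p = 4.08e-09). The water channel gene Aqp5 (gene ID 11830, chromosome 15, 99591028 to 99594829) rose 4.85-fold (log2 2.28, SE 0.13), and Chil1 rose 6.12-fold (log2 2.61, SE 0.35). Ugt1a6a rose 8.67-fold (log2 3.12, SE 0.35), but it shares exons with the other Ugt1a genes, so its reads are not certain to be its own. Among the genes that fell, Rasl11a (gene ID 68895, chromosome 5, 146845071 to 146847726) was 2.39-fold lower (log2 -1.26, SE 0.14), P3h2 1.99-fold lower (log2 -0.99, SE 0.085) and St6gal1 1.82-fold lower (log2 -0.86, SE 0.067).

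Of the 23 genes on the fixed list of cAMP and CREB targets, 12 were higher and 0 lower over all genes tested, and 16 were higher and 2 lower when adjusted over the list alone. Nr4a1 rose 3.39-fold (log2 1.76, SE 0.072), Rgs2 3.27-fold (log2 1.71, SE 0.15) and Sik1 1.77-fold (log2 0.83, SE 0.071). The list was higher as a set (camera adjusted p = 1.79e-16) and stayed so with adjusted p = 0.0362 with an estimated correlation. Of 19 basement membrane genes, 7 were lower and 0 higher (10 lower adjusted over the list alone), including the type IV collagen chains Col4a3 (log2 -0.67, SE 0.060), Col4a4 (log2 -0.55, SE 0.069) and Col4a5 (log2 -0.52, SE 0.051). This list was lower as a set (adjusted p = 1.97e-08), also with an adjusted p = 0.0403 with an estimated correlation. These 2 lists were the ones whose calls held with an estimated correlation among the 13 called in this comparison.

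The other 11 called lists lost their calls with an estimated correlation. Of 15 principal cell markers, 4 were higher and 0 lower (5 higher adjusted over the list alone): Aqp2, Tmem45b (1.48-fold), Avpr2 and Aqp3. The set test gave adjusted p = 0.000569, and adjusted p = 0.201 with an estimated correlation. The call of Avpr2, the V2 receptor (log2 0.45, SE 0.086, adjusted p = 0.00795), was lost without control-siRNA vehicle replicate 2 (adjusted p = 0.0530) or replicate 3 (0.0567), with a range over all alternatives of 6.13e-05 to 0.0567. That of Aqp3 (log2 1.19, SE 0.30, adjusted p = 0.0445) was lost without control-siRNA vehicle replicates 1 (0.150), 2 (0.0892) or 3 (0.172), control-siRNA dDAVP replicates 1 (0.168) or 2 (0.0867), Ctnnb1-siRNA vehicle replicate 2 (0.0667) or Ctnnb1-siRNA dDAVP replicate 1 (0.0586), with a range of 0.0169 to 0.172. Of 9 intercalated cell markers, 2 were higher (4 adjusted over the list alone), Atp6v0a4 at 2.02-fold and Aqp6 (log2 1.56), whose call was lost on log2 TPM (adjusted p = 0.0607) and on log2 TPM without small structural RNA (0.0527; range 2.70e-06 to 0.0607); the set test gave adjusted p = 0.00609, and adjusted p = 0.280 with an estimated correlation. Of 26 genes of protein kinase A signalling, 5 were higher, among them Pde4d (log2 1.94, SE 0.17), Akap12 (log2 1.34, SE 0.15) and Prkar2b (log2 0.56, SE 0.068), and 1 was lower, Pkia (log2 -0.46, named after its value was seen); adjusted over the list alone these were 6 and 1. That set gave adjusted p = 0.00496, and adjusted p = 0.394 with an estimated correlation. Of 20 renal ion transport genes, 4 were higher and 0 lower (5 higher adjusted over the list alone), including the sodium pump subunits Atp1b1 (1.69-fold) and Fxyd2 (2.48-fold); the set gave adjusted p = 0.00496, and adjusted p = 0.394 with an estimated correlation. Egfr (1.48-fold) was 1 of 3 higher genes among 20 of the MAPK feedback list (4 adjusted over the list alone; set adjusted p = 0.000837, adjusted p = 0.226 with an estimated correlation). Elovl6 (1.31-fold) was 1 of 2 higher among 17 lipid synthesis genes (5 adjusted over the list alone; set adjusted p = 0.00629, adjusted p = 0.123 with an estimated correlation). Cxcl5 (2.88-fold) and C3 (1.79-fold) were the 2 higher genes among 19 of the NF-kappaB list (3 adjusted over the list alone; set adjusted p = 0.0118, adjusted p = 0.400 with an estimated correlation). Of 33 genes of the G2 and M phases, edgeR called 0 (DESeq2 1 lower, voom 7, log2 TPM 4, log2 TPM without small structural RNA 1, and 3 without Ctnnb1-siRNA dDAVP replicate 3), 0 had a positive fold change, and the set was lower (adjusted p = 2.41e-07, adjusted p = 0.372 with an estimated correlation). Among 21 regulators of Aqp2 transcription 0 were higher and 1 was lower, Jun (3 higher and 1 lower adjusted over the list alone; set adjusted p = 0.0410, higher, and adjusted p = 0.280 with an estimated correlation). In this list the member called moved against the set. The call of Jun (log2 -0.31) was lost without control-siRNA vehicle replicates 2 (adjusted p = 0.131) or 3 (0.0536) and without control-siRNA dDAVP replicates 1 (0.0676) or 3 (0.125), with a range of 0.00189 to 0.131 over all alternatives.

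Lists that reflect the RNA itself moved in the same comparison. The 13 protein-coding genes of the mitochondrial genome gave 0 calls, 12 positive fold changes and a set adjusted p = 0.0341 (adjusted p = 0.777 with an estimated correlation). The 7 tested nuclear RNAs such as Malat1 gave 0 calls over all genes (2 higher adjusted over the list alone), 7 positive fold changes and a set adjusted p = 0.00496 (adjusted p = 0.123 with an estimated correlation).

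In edgeR's test 316 genes were higher and 151 lower in control-siRNA cells with dDAVP, of which 75 and 5 changed by at least 2-fold. The counts moved to 183 and 61 without control-siRNA vehicle replicate 2, 181 and 61 without replicate 3, 199 and 68 without control-siRNA dDAVP replicate 1, 209 and 58 without replicate 3, and 513 and 334 without Ctnnb1-siRNA dDAVP replicate 3. Genes called higher made up 67.67% of the calls on TMM-scaled counts, 56.3% with voom and 37.62% (161 higher, 267 lower) on log2 TPM, which shifts the median of all genes by -0.0549 (log2). On log2 TPM without small structural RNA the share was 61.11% (231 higher, 147 lower), with a median of all genes of -0.0123. Of the 58 genes named by rule and called here, 36 kept their calls without each of the 12 libraries in turn.

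The second comparison asked the same of cells with Ctnnb1 knocked down. Aqp2 rose from 8 reads in the 3 vehicle libraries to 513 reads in the 3 dDAVP libraries, a ratio of 60 (95% counting interval 30.2 to 140; 0.0614 CPM, SD 0.068, against 3.75 CPM, SD 0.434, n = 3 each; adjusted p = 1.76e-06). Of the 8 reads, 6 were in vehicle replicate 2, without which the log2 fold change of Aqp2 rose from 5.85 to 7.13, and over all alternatives it ranged from 2.47 to 7.13. The low end is again from log2 of TPM plus 1. Pde4b rose 8.71-fold (log2 3.12, SE 0.17), Baiap2l2 6.59-fold (log2 2.72, SE 0.13) and B3gnt7 (gene ID 227327, chromosome 1, 86303221 to 86307305) 5.67-fold (log2 2.50, SE 0.20, adjusted p = 3.24e-06). Ugt1a6a rose 8.11-fold and Chil1 5.40-fold. P3h2 fell 2.31-fold (log2 -1.21, SE 0.086), Rasl11a 2.31-fold (log2 -1.21, SE 0.14), Myo3b 2.37-fold (log2 -1.25, SE 0.20) and Fgf18 1.99-fold (log2 -0.99, SE 0.17).

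Of the 23 cAMP and CREB targets, 13 were higher and 0 lower (14 higher adjusted over the list alone), including Nr4a1 (2.31-fold), Pde4d (3.01-fold) and Cebpb (1.39-fold). The set gave adjusted p = 5.01e-17, and adjusted p = 0.0326 with an estimated correlation, the 1 call of 14 that held so. Without Ctnnb1-siRNA dDAVP replicate 3 the latter was 0.05, at the threshold. Of 19 basement membrane genes, 6 were lower and 0 higher (10 lower adjusted over the list alone), among them Col4a3 (1.54-fold) and Col4a4 (1.54-fold). The set gave adjusted p = 7.29e-08, and adjusted p = 0.0530 with an estimated correlation. Of 15 principal cell markers 4 were higher and 0 lower (8 higher adjusted over the list alone), including Tmem45b (1.65-fold); the set gave adjusted p = 6.33e-05, and adjusted p = 0.181 with an estimated correlation. Avpr2 (log2 0.43, SE 0.086, adjusted p = 0.0107) lost its call without Ctnnb1-siRNA vehicle replicate 1 (0.0704) or replicate 2 (0.0522), with a range of 0.000203 to 0.0704 over all alternatives. Of 27 interferon response genes, 3 were higher and 0 lower (11 higher adjusted over the list alone), and 26 had positive fold changes. The set gave adjusted p = 1.54e-08, and adjusted p = 0.254 with an estimated correlation, and reads of the Oas genes on this list are shared between close paralogs. Of 37 ribosomal protein genes, 1 was higher and 36 had positive fold changes; the set gave adjusted p = 2.69e-07, and adjusted p = 0.509 with an estimated correlation. Of 28 nuclear genes of oxidative phosphorylation 0 were called, and the set was higher (adjusted p = 0.0189, adjusted p = 0.651 with an estimated correlation). These groups were higher in the libraries with the highest mean share of small structural RNA, 2.39%.

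Of 9 intercalated cell markers 3 were higher (5 adjusted over the list alone), among them Atp6v0a4 (log2 0.85; set adjusted p = 0.0168, adjusted p = 0.481 with an estimated correlation). Fads2 (log2 0.33) was the 1 higher gene among 17 of lipid synthesis (4 adjusted over the list alone; set adjusted p = 0.0168, adjusted p = 0.181 with an estimated correlation). Among 33 genes of the G2 and M phases 1 was lower, and the set was lower (adjusted p = 6.33e-05, adjusted p = 0.509 with an estimated correlation). For 5 further lists the call was also lost without Ctnnb1-siRNA dDAVP replicate 3. Protein kinase A signalling had 4 higher genes, among them Akap12 (3.03-fold), and 1 lower, Pkia (set adjusted p = 0.00743, adjusted p = 0.481 with an estimated correlation, 0.0666 without that library). The NF-kappaB list had 2 higher genes, Cxcl5 (1.94-fold) and C3 (1.74-fold; set adjusted p = 0.0168, adjusted p = 0.481 with an estimated correlation, 0.0666 without that library). Of 20 genes of the unfolded protein response, 3 were higher over all genes and over the list alone (set adjusted p = 0.0189, adjusted p = 0.481 with an estimated correlation, 0.0641 without that library). Of 20 renal ion transport genes, 4 were higher (5 adjusted over the list alone), among them Fxyd2 (2.51-fold) and Trpv4 (1.36-fold; set adjusted p = 0.0229, adjusted p = 0.509 with an estimated correlation, 0.351 without that library). Of 35 Wnt pathway components 1 was higher, the receptor gene Fzd4 (1.86-fold), while 6 had positive fold changes and the set was lower (adjusted p = 0.0334, adjusted p = 0.481 with an estimated correlation, 0.128 without that library). Without it the S phase list was called higher (adjusted p = 0.0115), which it was not with all libraries (0.0729).

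In edgeR's test 344 genes were higher and 115 lower, of which 69 and 13 changed by at least 2-fold. Without Ctnnb1-siRNA vehicle replicate 1 the counts were 202 and 50, and without replicate 2 they were 185 and 31. The lower genes numbered 56 without Ctnnb1-siRNA vehicle replicate 3 and 76 without Ctnnb1-siRNA dDAVP replicate 2. Genes called higher made up 74.95% of the calls, and 61.76% on log2 TPM. Of the 63 genes named by rule and called here, 37 kept their calls without each of the 12 libraries in turn.

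The interaction asked whether the response to dDAVP differs between the siRNAs, the question the series is built on. In edgeR's test 0 of 16508 genes were called, with 829 genes at an unadjusted p under 0.05 where 825.4 would be given by chance. The latter count was 1713 without Ctnnb1-siRNA dDAVP replicate 3, 1400 without control-siRNA dDAVP replicate 2 and 514 without Ctnnb1-siRNA vehicle replicate 1, each with 0 genes called, so its closeness to the chance count rests on the libraries used. DESeq2 called 1 gene, Nr4a1, and voom called 0, with 754 and 1919 genes at an unadjusted p under 0.05. Nr4a1 (gene ID 15370, chromosome 15, 101253902 to 101274795) rose 3.39-fold in control-siRNA cells and 2.31-fold after knockdown, a difference of log2 -0.55 (SE 0.10) with an edgeR adjusted p of 0.865 and a DESeq2 adjusted p of 0.00859, the range over all alternatives being 0.00859 to 1. For Aqp2 the difference was log2 -2.53 (SE 1.16, adjusted p = 0.918), a value that rests on the 2 and 8 vehicle reads and ranged from -5.19 to -0.74 over all alternatives. The end at -0.74 is from log2 of TPM plus 1, which shrinks changes near 0. With dDAVP, Aqp2 had 1.63 times (95% counting interval 1.45 to 1.82) as many normalised reads in control-siRNA cells as after knockdown; the exact permutation p was 0.1 (two-sided), the smallest possible for 3 against 3, and edgeR's adjusted p was 0.287. The other genes with the smallest unadjusted p, none called, included Gng13 (log2 6.05, SE 1.23), Cacna2d4 (log2 6.71, SE 1.47) and Entpd3 (log2 0.80, SE 0.19) upwards and H4c14 (log2 -0.49) downwards, each with an adjusted p of 0.918. Gng13 and Cacna2d4 had 0 CPM in the control-siRNA dDAVP libraries and at most 0.383 and 0.358 CPM in any other, and their values ranged from 0.92 to 6.35 and from 4.82 to 7.18 over all alternatives.

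The size of the whole response was compared over the 1133 genes called in the average dDAVP effect. The slope of the response after knockdown on that in control-siRNA cells was 0.964 (jackknife SE 0.205 over libraries, 95% interval 0.561 to 1.37). The median signed difference was -0.01 (log2, SE 0.068, 95% interval -0.14 to 0.13), and 52.69% of the genes responded less after knockdown. A fry test of the signed genes found no difference at 0.05. A response score, the mean log2 CPM of raised minus lowered genes, was -0.77 (SD 0.059) and 0.11 (SD 0.053) in control-siRNA cells with vehicle and dDAVP, and -0.66 (SD 0.016) and 0.19 (SD 0.16) after knockdown (n = 3 each). The interval of the slope spans responses from 0.561 to 1.37 times the control response. Both intervals are approximate, since the jackknife took the libraries as 1 sample and not as 4 groups of 3. A difference of about this size may therefore not be detectable with these samples.

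**Figure D2:**
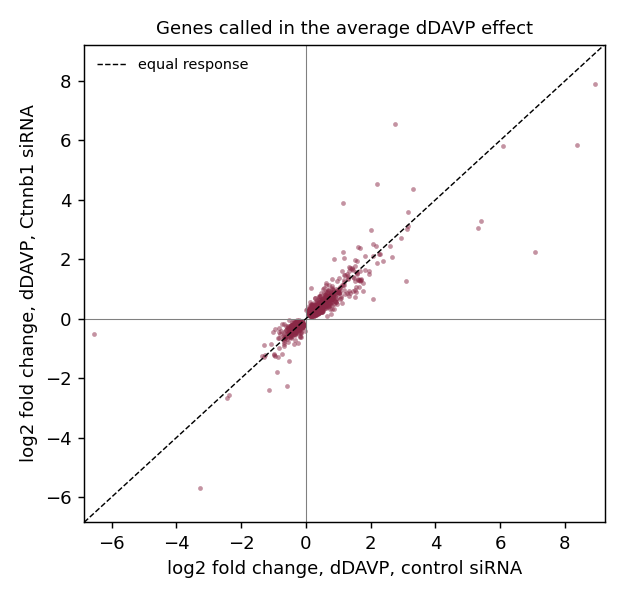
Log2 fold change with dDAVP in Ctnnb1-siRNA cells against that in control-siRNA cells, 1 point per gene called in the average dDAVP effect (1133 genes), with a dashed line for equal responses. The plotted values are from edgeR. The slope, computed on group means of log2 CPM instead, is 0.964 with an approximate 95% interval of 0.561 to 1.37.

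**Figure D3:**
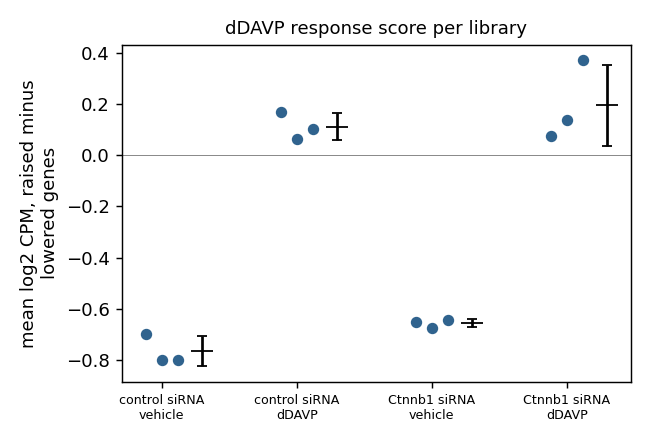
Score of the dDAVP response (mean log2 CPM of genes raised minus genes lowered) in each of the 12 libraries by group, with dots for libraries and bars for the mean ± SD (n = 3). The genes were chosen on these libraries, so the rise with dDAVP is built in, and the group means with dDAVP are 0.11 and 0.19.

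The calls of the 2 dDAVP comparisons shared 226 higher and 57 lower genes, where independent lists would share 6.58 and 1.05, and 0 genes were called in opposite directions. Of the 467 genes called in control-siRNA cells, 455 changed in the same direction after knockdown, and 449 of the 459 called after knockdown did so in control-siRNA cells.

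The third question was what Ctnnb1 siRNA does without the agonist. With vehicle, Ctnnb1 siRNA raised Spp1 (gene ID 20750, chromosome 5, 104435111 to 104441053), the gene of osteopontin, 1.73-fold from 39.7 CPM (SD 6.20) to 68.7 CPM (SD 5.85; log2 0.79, SE 0.11, n = 3 each, adjusted p = 0.00507). The semaphorin and VEGF co-receptor gene Nrp2 (gene ID 18187, chromosome 1, 62703317 to 62818692) rose 1.62-fold (log2 0.69, SE 0.077, adjusted p = 0.000473) and Arhgap40 1.60-fold (log2 0.67, SE 0.092). The immediate early genes Jun (gene ID 16476, chromosome 4, 95049036 to 95052222) and Arc (gene ID 11838, chromosome 15, 74669081 to 74672570) fell 1.63-fold (log2 -0.71, SE 0.068, adjusted p = 0.000157) and 1.59-fold (log2 -0.67, SE 0.073, adjusted p = 0.000448), and Parm1 fell 1.57-fold. These genes and Ctnnb1 kept their calls in every alternative, 7 of the 20 genes named by rule and called here. Rnf43 (gene ID 207742, chromosome 11, 87663087 to 87735539), a negative regulator of Wnt receptors and 1 of the 8 tested Wnt target genes, was 3.43-fold lower (2.32 CPM, SD 0.201, against 0.681 CPM, SD 0.408; log2 -1.78, SE 0.30, adjusted p = 0.0136). Its call was lost without control-siRNA vehicle replicates 1 (adjusted p = 0.0631), 2 (0.0625) or 3 (0.0745) and without Ctnnb1-siRNA vehicle replicates 2 (0.0890) or 3 (0.0876), with a range of 4.08e-05 to 0.0890 over all alternatives. It was the 1 Wnt target gene called (1 higher and 1 lower adjusted over the list alone; set adjusted p = 0.797).

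Of 23 glycolysis and hypoxia genes, 4 were higher and 0 lower with vehicle, 11 were higher when adjusted over the list alone, and 23 had positive fold changes with a median of log2 0.17. They included the hexokinase gene Hk2 (log2 0.57, SE 0.088, adjusted p = 0.00867) and the collagen prolyl hydroxylase gene P4ha1 (log2 0.39, SE 0.071, adjusted p = 0.0230). The set gave adjusted p = 2.97e-12, and adjusted p = 0.191 with an estimated correlation. The call of Hk2 was lost without control-siRNA vehicle replicates 2 (0.0690) or 3 (0.0745) or Ctnnb1-siRNA vehicle replicate 3 (0.0591), with a range of 9.87e-07 to 0.116 over all alternatives. That of P4ha1 was lost without control-siRNA vehicle replicates 1 (0.109), 2 (0.102) or 3 (0.132) or Ctnnb1-siRNA vehicle replicates 1 (0.0704), 2 (0.0929) or 3 (0.132), with a range of 9.86e-05 to 0.164. Of 19 genes of the NF-kappaB list 0 were called over all genes and 5 were higher adjusted over the list alone (set adjusted p = 2.80e-06, adjusted p = 0.191 with an estimated correlation). Of 20 MAPK feedback genes 1 was higher (3 adjusted over the list alone; set adjusted p = 3.43e-05, adjusted p = 0.191 with an estimated correlation). Of 16 TGF-beta and BMP targets 2 were lower, among them Id1 (1 higher and 4 lower adjusted over the list alone; set adjusted p = 0.00983, adjusted p = 0.394 with an estimated correlation). The call of Id1 (log2 -0.65, SE 0.10, adjusted p = 0.00809) was lost without control-siRNA vehicle replicate 3 (0.0745) or Ctnnb1-siRNA vehicle replicate 3 (0.0624), with a range of 2.91e-06 to 0.0745. Of 27 interferon response genes edgeR called 0 (DESeq2 0, voom 0, and 1 lower without Ctnnb1-siRNA dDAVP replicate 3) and 2 had positive fold changes, the set being lower (adjusted p = 2.80e-06, adjusted p = 0.394 with an estimated correlation). Sets without a called gene were also higher for 24 sterol synthesis genes (1 adjusted over the list alone; adjusted p = 0.00983, adjusted p = 0.658 with an estimated correlation), 37 ribosomal protein genes (adjusted p = 0.0284, adjusted p = 0.859 with an estimated correlation) and 7 nuclear RNAs (adjusted p = 0.0156, adjusted p = 0.191 with an estimated correlation). Small structural RNA took 1.58% and 2.18% of reads in the means of the same groups. Without Ctnnb1-siRNA dDAVP replicate 3, which enters this comparison only through the shared spread and scaling, the YAP target list was called lower too (adjusted p = 0.0234 against 0.0600).

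In edgeR's test 34 genes were higher and 37 lower with vehicle, and 1 and 4 of them changed by at least 2-fold. Without control-siRNA vehicle replicate 2 the counts were 10 and 11, without replicate 3 they were 11 and 11, and without replicate 1 the lower genes were 24. Without Ctnnb1-siRNA vehicle replicates 1, 2 and 3 they were 10 and 14, 18 and 18, and 8 and 13. Without Ctnnb1-siRNA dDAVP replicate 3, a library outside the comparison, they were 97 and 83. Of the calls 47.89% were higher, and 28.85% on log2 TPM (15 higher, 37 lower).

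With dDAVP, Arc (1.61-fold; log2 -0.69, SE 0.073, adjusted p = 0.000518) and Jun (1.54-fold; log2 -0.62, SE 0.069, adjusted p = 0.000738) were again lower after Ctnnb1 siRNA, and with Ctnnb1 they were the 3 of 16 called genes named by rule that kept their calls in every alternative. Rnf43 was 3.20-fold lower (log2 -1.68, SE 0.31, adjusted p = 0.0296, range over all alternatives 0.000254 to 0.191). Its call was lost without control-siRNA vehicle replicates 1 (0.0508), 2 (0.0575) or 3 (0.0632), control-siRNA dDAVP replicates 1 (0.0914), 2 (0.0506) or 3 (0.132) and Ctnnb1-siRNA dDAVP replicates 1 (0.0506) or 2 (0.107). The T-cadherin gene Cdh13 was 1.47-fold higher (log2 0.56, SE 0.087, adjusted p = 0.0125), a call lost without control-siRNA dDAVP replicates 1 (0.0750) or 3 (0.0584; range 1.20e-05 to 0.184). The E-box transcription factor gene Tcf4, which is not the Wnt effector Tcf7l2, was 1.55-fold lower (log2 -0.64, SE 0.099, adjusted p = 0.0125), a call lost without control-siRNA dDAVP replicates 1 (0.0750) or 3 (0.0893) or Ctnnb1-siRNA dDAVP replicate 1 (0.0531; range 7.52e-07 to 0.179). Aqp2 was not called with vehicle either (2 against 8 reads; adjusted p = 0.759, exact permutation p = 0.4, two-sided).

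Of 23 glycolysis and hypoxia genes 1 was higher with dDAVP, P4ha1 (1.36-fold), 12 were higher adjusted over the list alone, and 23 had positive fold changes (set adjusted p = 1.74e-10, adjusted p = 0.312 with an estimated correlation). The call of P4ha1 was lost without control-siRNA dDAVP replicates 1 (0.0766) or 3 (0.120), with a range of 7.10e-06 to 0.229 over all alternatives. Of 37 ribosomal protein genes edgeR called 0 over all genes (DESeq2 5 higher, voom 6, and 2 without Ctnnb1-siRNA dDAVP replicate 3), 21 were higher adjusted over the list alone, and 37 had positive fold changes with a median of log2 0.16 (set adjusted p = 1.81e-14, adjusted p = 0.440 with an estimated correlation). Their share of all reads was 4.47% (SD 0.265) in control-siRNA and 4.95% (SD 0.276) in Ctnnb1-siRNA libraries with dDAVP (n = 3 each), beside small structural RNA at 2.07% and 2.39%. Of 23 cAMP and CREB targets 2 were lower, among them the insulin receptor substrate gene Irs2 at 1.33-fold (1 higher and 8 lower adjusted over the list alone; set adjusted p = 0.000452, adjusted p = 0.330 with an estimated correlation). The call of Irs2 was lost without control-siRNA dDAVP replicates 1 (0.0750) or 3 (0.0621) or Ctnnb1-siRNA dDAVP replicate 1 (0.0506), with a range of 7.69e-06 to 0.188. Of 8 Wnt target genes 1 was lower, Rnf43 (2 lower adjusted over the list alone; set adjusted p = 0.00475, adjusted p = 0.312 with an estimated correlation). Of 35 Wnt pathway components 0 were called and the set was lower (adjusted p = 0.00152, adjusted p = 0.330 with an estimated correlation). Of 19 YAP targets 1 was lower (1 higher and 6 lower adjusted over the list alone; set adjusted p = 0.0369, adjusted p = 0.330 with an estimated correlation). Of 24 lysosome genes 1 was higher (2 adjusted over the list alone; set adjusted p = 0.00152, adjusted p = 0.330 with an estimated correlation). Sets higher without a called gene were the NF-kappaB list (8 higher adjusted over the list alone; adjusted p = 0.000166, adjusted p = 0.330 with an estimated correlation), oxidative phosphorylation (adjusted p = 0.000290, adjusted p = 0.724 with an estimated correlation), the S phase list (adjusted p = 0.0110, adjusted p = 0.567 with an estimated correlation) and the G2 and M phase list (adjusted p = 0.0432, adjusted p = 0.727 with an estimated correlation). Without Ctnnb1-siRNA dDAVP replicate 3, calls were added for the regulators of Aqp2 transcription (adjusted p = 0.0327, lower), sterol synthesis (0.0375, higher) and the mitochondrial genome (0.000181, lower).

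In edgeR's test 20 genes were higher and 24 lower with dDAVP, and 1 and 5 of them changed by at least 2-fold. Without control-siRNA vehicle replicate 3 or Ctnnb1-siRNA vehicle replicate 2 the higher genes were 12 and 13, and without control-siRNA dDAVP replicate 2 the lower genes were 44. Without control-siRNA dDAVP replicates 1 and 3 the counts were 0 and 5, and 1 and 7. Without Ctnnb1-siRNA dDAVP replicates 1 and 3 they were 9 and 10, and 106 and 111. Of the calls 45.45% were higher, and 20% on log2 TPM (4 higher, 16 lower). The calls shared 11 higher and 15 lower genes with those made with vehicle, where independent lists would share 0.0412 and 0.0538, and 0 were opposite.

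Averaged over both siRNAs, dDAVP raised 714 genes and lowered 419. Averaged over both treatments, Ctnnb1 siRNA raised 155 and lowered 150. The genes lowered by dDAVP were 274 without control-siRNA vehicle replicate 2, 250 without replicate 3, 271 without control-siRNA dDAVP replicate 3 and 267 without Ctnnb1-siRNA vehicle replicate 2. The siRNA counts were 95 and 89 without control-siRNA vehicle replicate 2, 91 and 86 without replicate 3, 100 and 86 without control-siRNA dDAVP replicate 3, 99 and 87 without Ctnnb1-siRNA vehicle replicate 2, 91 and 84 without replicate 3 and 338 and 273 without Ctnnb1-siRNA dDAVP replicate 3. Without control-siRNA dDAVP replicate 1 the genes lowered by siRNA were 97. Genes called higher made up 63.02% of the dDAVP calls and 30.36% on log2 TPM (327 higher, 750 lower), and 50.82% of the siRNA calls against 40 higher and 207 lower on log2 TPM. Without small structural RNA, log2 TPM gave 479 higher and 520 lower for dDAVP, and 82 and 174 for siRNA. The estimates of the 2 averages are independent when the spread is equal in all groups. Both tests share each gene's read depth and spread estimate, so their calls can overlap more than independent lists in either direction. The averages shared 45 genes higher in both and 28 lower in both, where independent lists would share 6.70 and 3.81. Higher in both were Oit1 (log2 0.82 with dDAVP, 0.42 with siRNA), Adh7 (1.04 and 0.64), Selenbp1 (0.77 and 0.29), Lgals3 (0.48 and 0.45) and the quinone reductase gene Nqo1 (0.39 and 0.36). Lower in both were Nrp1 (-0.50 and -0.56), St6gal1 (-0.76 and -0.28), Nrep (-0.60 and -0.43), Fras1 (-0.46 and -0.31) and Nedd9 (-0.25 and -0.21). In the opposite quadrants 16 genes were raised by dDAVP and lowered by siRNA (6.49 by independent lists, Fisher's exact one-sided p = 0.000788), among them Irs2 (0.39 and -0.38) and Fos (0.83 and -0.33), and 4 went the other way (3.93), Bst1, Gng13, P4ha1 and Il18r1. The Fisher test takes genes as independent, which they are not, so its p may be too small. Overlap in the same direction was 6.94 times that of independent lists and overlap in opposite directions 1.92 times. Same-direction overlap ranged from 3.39 times with voom (162 genes, 92 in opposite directions) to 11.1 times without a low-count filter (63 and 18), with 5.36 times in DESeq2 (137 and 50). On log2 TPM it was 4.94 times, but with 6 genes higher and 52 lower in both, and without small structural RNA 6.18 times, with 20 and 35. The genes higher or lower in both were 43 without control-siRNA vehicle replicate 2, 39 without replicate 3, 40 without control-siRNA dDAVP replicate 3, 38 without Ctnnb1-siRNA vehicle replicate 2, 41 without replicate 3 and 122 without Ctnnb1-siRNA dDAVP replicate 3, against 73 with all libraries. The genes in the opposite quadrants, 20 with all libraries, were 12 without control-siRNA vehicle replicate 1, 11 without replicate 2 or 3, 9 without control-siRNA dDAVP replicate 3, 11 without Ctnnb1-siRNA vehicle replicate 3 and 54 without Ctnnb1-siRNA dDAVP replicate 3, and 13 without control-siRNA dDAVP replicate 1 or Ctnnb1-siRNA vehicle replicate 2.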

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

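The tests of libraries not used for the calls, of gene length and of lists without a library were added after the data were seen, and the tests of small structural RNA and of other splits for the interaction were chosen only after their results were seen. The interaction called 0 genes in edgeR (829 at an unadjusted p under 0.05, but 1713 without Ctnnb1-siRNA dDAVP replicate 3, 1400 without control-siRNA dDAVP replicate 2 and 514 without Ctnnb1-siRNA vehicle replicate 1; DESeq2 1, voom 0, log2 TPM 0, and 1 without small structural RNA), but 7 of the 36 fixed lists differed between the siRNAs in their response to dDAVP by the set test. None of the 7 held with an estimated correlation. Lower after knockdown were the Wnt target genes (adjusted p = 0.0348, adjusted p = 0.628 with an estimated correlation; median log2 -0.19, 1 of 8 positive) and the MAPK feedback genes (adjusted p = 8.47e-05, adjusted p = 0.628 with an estimated correlation; median log2 -0.19, 2 of 20 positive). Higher were the interferon response (adjusted p = 9.18e-06, adjusted p = 0.862 with an estimated correlation; median log2 0.23, 25 of 27 positive), ribosomal protein genes (adjusted p = 4.74e-06, adjusted p = 0.862 with an estimated correlation; median log2 0.12, 35 of 37 positive) and oxidative phosphorylation (adjusted p = 0.00235, adjusted p = 0.862 with an estimated correlation; median log2 0.08, 26 of 28 positive). The S phase list (adjusted p = 0.00381, adjusted p = 0.862 with an estimated correlation; median log2 0.09, 25 of 31 positive) and the unfolded protein response (adjusted p = 0.0387, adjusted p = 0.862 with an estimated correlation; median log2 0.08, 17 of 20 positive) were higher too. The interferon median went to 0.15 (adjusted p = 0.0303) without Ctnnb1-siRNA dDAVP replicate 3. The ribosomal median went to 0.063 without control-siRNA vehicle replicate 1 and to 0.078 without Ctnnb1-siRNA dDAVP replicate 2, and to 0.080 with a length correction and 0.077 on log2 TPM without small structural RNA. The medians of the other 5 lists were not tested without each library. Without Ctnnb1-siRNA dDAVP replicate 3 the unfolded protein response was no longer called (adjusted p = 0.0638) and the mitochondrial genome was called (adjusted p = 9.91e-05).

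The average dDAVP and Ctnnb1-siRNA effects ran the same way, with 73 shared genes in the same direction, 6.94 times as many as independent lists would give. The 2 tests share each gene's read depth and spread estimate, so part of this excess may need no common direction. Overlap in opposite directions was 1.92 times that of independent lists. A correction for gene length left the same-direction overlap at 5.46 times, above the 3 times set in advance. This argues against a length trend as the whole cause. When the siRNA effect was taken from libraries not used to call the dDAVP effect, its median signed value was 0.05 (log2) over 40 draws and above 0 in 39, but the lowest was -0.014. In the reverse test, the dDAVP effect on siRNA-called genes in other libraries was above 0 in 32 of 40 draws, with a lowest of -0.05, and the condition set in advance was every draw above 0, so an unequal spread between the groups stays open. A shared programme of both treatments is a hypothesis that no test here separates from that spread.

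Glycolysis and hypoxia genes were higher after Ctnnb1 siRNA, with 9 of 23 called and a median of log2 0.17 in the average effect (adjusted p = 3.72e-15, adjusted p = 0.232 with an estimated correlation). The lowest median without any 1 of the 12 libraries was 0.154 and the median with a length correction was 0.164, both above 0.5 of the value, the bound set in advance, which argues against 1 library or gene length as the whole cause. The values were smaller on log2 TPM (median 0.089, 3 called) and on log2 TPM without small structural RNA (0.13, 7 called), while voom called 16. Differences in oxygen or cell density between the cultures were not measured, so an effect of the siRNA itself and one of culture conditions both stay open.

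Of 37 ribosomal protein genes edgeR called 0 after Ctnnb1 siRNA with dDAVP (DESeq2 5 higher, voom 6, and 2 without Ctnnb1-siRNA dDAVP replicate 3), but 37 had positive fold changes with a median of log2 0.16, and the set was higher only with the preset correlation (adjusted p = 1.81e-14, adjusted p = 0.440 with an estimated correlation). The lowest median without any 1 of the 6 libraries was 0.128 and the median with a length correction was 0.123, both above 0.5 of the value, which argues against 1 library or gene length as the whole cause. The median was smaller on log2 TPM (0.083) and on log2 TPM without small structural RNA (0.10). With the share of small structural RNA in each library as a covariate, the group difference of the list's median went from 0.12 (SE 0.058) to 0.0844 (log2, SE 0.035), closer to 0.5 of the first value than its error, so the condition was not met. The difference in RNA composition and an effect of the siRNA therefore cannot be told apart for these genes, since the share is also highest on average in the Ctnnb1-siRNA dDAVP group. The list's median log2 CPM was 9.038, 9.168 and 9.061 in control-siRNA dDAVP replicates 1 to 3. In Ctnnb1-siRNA dDAVP replicates 1 to 3 it was 9.207, 9.291 and 9.122. These values overlap between the siRNAs but not between the sides of the split with 1619 calls, given below. Leaving out 1 library at a time cannot test such a split, which stays open too.

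Other splits of the libraries were refitted as a test of chance. For the average dDAVP effect, the real split called 1133 genes and the highest other called 1, so that 1 of 100 splits reached the real count. This is the smallest share these splits can give, and it argues against a chance split of these libraries. If the replicates are technical, it does not bear on chance between cultures. For the average siRNA effect, the real split called 305 and 2 of 100 splits reached it, the other calling 523 and the next 76. The share is under 0.05, but a split with more calls than the real one also points to a structure of the samples. For the interaction the real count is 0, which all 100 of 100 splits reach by construction (highest other 1), so that test is void and nothing is drawn from it. With 10 splits for each pairwise comparison, the splits are too few for a share under 0.05: the real and highest other counts were 467 and 0 for dDAVP in control-siRNA cells (1 split), 459 and 1 in Ctnnb1-siRNA cells (1 split), 71 and 0 for siRNA with vehicle (1 split), and 44 and 1619 for siRNA with dDAVP (2 splits). The split with 1619 calls set control-siRNA dDAVP replicates 1 and 3 and Ctnnb1-siRNA dDAVP replicate 3 against control-siRNA dDAVP replicate 2 and Ctnnb1-siRNA dDAVP replicates 1 and 2, which points to a structure of the samples that the groups do not give. Small structural RNA took 1.67%, 2.05% and 1.60% of reads on the first side and 2.49%, 2.49% and 3.07% on the second. The counts of Ctnnb1 fitted the labels in all 6 of these libraries.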

How the results depend on the processing

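The length correction, log2 TPM without small structural RNA and lists without a library were chosen after seeing the data. No direction was reversed, in 0 of the 1827 values of named genes under other settings and 0 of the 2016 without a library. Most of these genes were picked because they were called in these same libraries, so the lack of reversals is largely built in. Of the values, 168 and 353 lost their calls, and 1 gained one (Nr4a1 in the interaction with DESeq2, 1 gene lower). Of 159 results of lists called in the pairwise comparisons and the interaction, 86 lost their calls under other list settings. Of 53 without Ctnnb1-siRNA dDAVP replicate 3, 6 did. Lists of the average effects, such as the osmotic list that also lost its call without that library, are not in these counts. The response ratio and the median signed difference stayed within their errors in 3 other settings. They did so without each library too, but this says little, since the errors were computed from those same values.

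Higher and lower genes are given in that order. DESeq2 called 504 and 258 genes for dDAVP in control-siRNA cells, 523 and 205 in Ctnnb1-siRNA cells, 97 and 80 for siRNA with vehicle, 133 and 104 with dDAVP, and 302 and 280 for the average siRNA effect. Of the calls reported, 459 of 467, 457 of 459, 71 of 71 and 42 of 44 were among them in the pairwise comparisons. Log2 TPM kept 252, 173, 33 and 16 of these calls, and fitting the 2 groups alone kept 435, 254, 70 and 5. In simulated data DESeq2 gave 31 false calls beside 163 recovered genes. With voom the counts were 706 and 548 for dDAVP in control-siRNA cells, 207 lower in Ctnnb1-siRNA cells, 118 and 114 for siRNA with vehicle, 134 and 113 with dDAVP, 790 lower for the average dDAVP effect and 466 and 394 for the average siRNA effect. Fitting the 2 groups compared alone gave 218 and 48 for dDAVP in Ctnnb1-siRNA cells, 135 and 90 for siRNA with vehicle and 0 and 5 with dDAVP (with dDAVP, 5 of the 44 calls were shared). On log2 TPM the counts were 161 and 267 for dDAVP in control-siRNA cells, 126 higher in Ctnnb1-siRNA cells, 15 higher for siRNA with vehicle and 4 with dDAVP, 327 and 750 for the average dDAVP effect and 40 higher for the average siRNA effect. Without small structural RNA, which took 10.2% to 14.3% of TPM by group mean, they were 203 higher for dDAVP in Ctnnb1-siRNA cells, 22 higher for siRNA with vehicle, 8 with dDAVP, 1 lower for the interaction and 82 higher for the average siRNA effect. The length correction gave 173 lower for dDAVP in Ctnnb1-siRNA cells, 61 higher for siRNA with vehicle, and 48 and 46 with dDAVP. For dDAVP in control-siRNA cells log2 TPM without small structural RNA gave 231 and 147, so most calls were again higher. Apart from this setting, the cause of the differences was not tested. With an estimated correlation 2, 1, 0, 0, 0, 2 and 0 lists were called for the 4 pairwise comparisons in this order, the interaction, the average dDAVP and the average siRNA effect, and with fry 6 for dDAVP in Ctnnb1-siRNA cells, 0 for siRNA with vehicle, 2 with dDAVP, 0 for the interaction and 6 for the average siRNA effect.

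Without 1 library the higher and lower genes ranged from 181 to 513 and 58 to 334 for dDAVP in control-siRNA cells, 185 to 359 and 31 to 154 in Ctnnb1-siRNA cells, 8 to 97 and 11 to 83 for siRNA with vehicle, and 0 to 106 and 5 to 111 with dDAVP. They ranged from 557 to 766 and 250 to 510 for the average dDAVP effect, and 91 to 338 and 84 to 273 for the average siRNA effect, and were 0 for the interaction without each library. Apart from the higher genes for dDAVP in Ctnnb1-siRNA cells and the interaction, the highest counts came without Ctnnb1-siRNA dDAVP replicate 3. This includes siRNA with vehicle and dDAVP in control-siRNA cells, which do not hold that library. There it can act only through the spread and scaling shared by the fit of all 12 libraries. Fitting the 2 groups compared alone gave 135 and 90 for siRNA with vehicle, against 34 and 37. For dDAVP in control-siRNA cells it gave 393 and 203, against 316 and 151. Why that library differs was not tested.

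With the replicate number as a block the counts were 280 and 128, 318 and 97, 24 and 29, and 15 and 23 in the pairwise comparisons. The numbers do not pair the libraries: residuals of same-number pairs had correlations across genes of -0.0864 to 0.0719, and 3 of 12 libraries were closest to their own number. Depth limits the vehicle level of Aqp2, where the response rests on 2 and 8 reads. In simulated data with 200 changed genes the smallest interactions were recovered for 10% of genes. With fewer changed genes the share may be lower.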

Other observations

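The list of NRF2 targets and the test of Aqp5 reads were chosen only after their results were seen. Markers of cells other than those of the collecting duct gave no called set for the average dDAVP effect: adjusted p = 0.188 for 2 proximal tubule genes, 0.930 for 3 of the loop and distal tubule, 0.779 for 3 fibroblast genes, 0.556 for 4 leukocyte genes and 0.884 for 4 endothelial genes. The same held for the average siRNA effect (0.809, 0.489, 0.251, 0.238 and 0.552). No called set was found either for 26 genes of Aqp2 trafficking (dDAVP 0.460, siRNA 0.387), 22 of adherens junctions and desmosomes (0.556 and 0.489), 24 of tight junctions (0.779 and 0.604), 13 of mesenchymal transition (0.779 and 0.387) or 21 p53 targets (0.240 and 0.251). Among them Tjp3 (log2 0.25) and Cldn2 (log2 1.07) rose and Cldn1 (log2 -0.51) fell with dDAVP on average, and the p53 target Sesn2 (log2 0.46) rose, genes named after their values were seen. Of 9 osmotic response genes 3 were higher with dDAVP on average, with Slc5a3, the inositol transporter gene, at log2 0.54 and Hspa1a and Hspa1b, similar paralogs that may share reads, at 0.17 and 0.21. That set gave adjusted p = 0.0428, adjusted p = 0.434 with an estimated correlation and 0.215 without Ctnnb1-siRNA dDAVP replicate 3.

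Averaged over both siRNAs, the response of the G2 and M phase genes to dDAVP included 5 lower genes of 33 (7 adjusted over the list alone; adjusted p = 3.01e-08, adjusted p = 0.348 with an estimated correlation). That count was 1 without control-siRNA vehicle replicate 3, 2 without vehicle replicate 1 or 2 or dDAVP replicate 1 or 3 of control siRNA or vehicle replicate 3 of Ctnnb1 siRNA, and 3 without Ctnnb1-siRNA vehicle replicate 2 or dDAVP replicate 1. It was 9 with voom, 19 on log2 TPM and 10 on log2 TPM without small structural RNA. The cAMP and CREB targets (14 higher; adjusted p = 1.18e-17, adjusted p = 0.0287 with an estimated correlation) and basement membrane genes (8 lower; adjusted p = 2.03e-09, adjusted p = 0.0287 with an estimated correlation) were the 2 of 14 called lists that held so. Averaged over both treatments, Ctnnb1 siRNA lowered 6 of 23 cAMP and CREB targets, among them Fos (log2 -0.33) and Id3 (log2 -0.56; adjusted p = 0.00833, adjusted p = 0.360 with an estimated correlation). It lowered 4 of 16 TGF-beta and BMP targets (adjusted p = 0.00833, adjusted p = 0.346 with an estimated correlation) and 3 of 19 YAP targets, Ccn1, Crim1 and Tgfb2 (adjusted p = 0.0119, adjusted p = 0.346 with an estimated correlation). It raised 4 of 19 genes of the NF-kappaB list, Cxcl1, Cxcl5, Cxcl16 and Il34 (adjusted p = 1.19e-07, adjusted p = 0.232 with an estimated correlation). The median, the mean and the set test differed in sign for 6 and 3 lists in the dDAVP comparisons with control and Ctnnb1 siRNA, 6 and 2 in the siRNA comparisons with vehicle and dDAVP, 9 in the interaction and 9 and 7 in the average dDAVP and siRNA effects, with 0 of them called. The calls of the single genes named here for the average effects were not tested without each library.

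After Srxn1 (log2 0.74) and Nqo1 (log2 0.39) were seen among the genes raised by dDAVP on average, 1 list of NRF2 target genes was written and those 2 genes were left out of the test. Of the other 22 genes, 14 were higher and 0 lower, and 22 had positive fold changes with a median of log2 0.25. The list was higher with a camera p of 1.03e-17, and of 4.21e-05 with an estimated correlation, and included Gclc (0.47), Txnrd1 (0.32), Gsta4 (0.62) and Cbr3 (0.74). With each siRNA 9 of its genes were higher and 0 lower, and the interaction called 0 of them. The list was also higher in the average siRNA effect (1 higher, 16 of 22 positive, median log2 0.08, camera p of 0.000118, and of 0.00689 with an estimated correlation), so its rise is not limited to dDAVP. That dDAVP raises an NRF2 programme in these cells is a hypothesis, since it was found and tested on the same data, and NRF2 protein was not measured.

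Aqp5, Aqp6 and Faim2 lie within 100 kb of Aqp2, and of the 4 tested genes there other than Aqp2 and Gm34765, 3 rose with dDAVP on average: Aqp5 (log2 2.23, SE 0.093), Aqp6 (log2 1.32) and Faim2 (log2 1.22, adjusted p = 0.0312), while Racgap1 did not (log2 -0.06, adjusted p = 0.331). Gm34765 overlaps Aqp2, Aqp5 and Aqp6, so their reads may not be told apart. It rose too (log2 4.20, adjusted p = 0.000498), with group means of at most 0.421 CPM. Read-through from Aqp2 was tested as a source of the Aqp5 reads. Aqp5 had more reads than Aqp2 in 12 of 12 libraries, but the 6 vehicle libraries, with 0 to 6 Aqp2 reads, say nothing about the rise with dDAVP. In the 6 dDAVP libraries Aqp5 had 748 to 947 reads and Aqp2 155 to 302, which argues only against read-through as the source of all Aqp5 reads. Aqp6 had fewer reads than Aqp2 in those 6 libraries (96 to 193), so read-through stays open for Aqp6, and a shared response of the neighbouring genes is a hypothesis.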
